A study of Drosophila melanogaster with 12 samples.

How the data were processed

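Poly(A) RNA of Drosophila melanogaster was sequenced from 12 samples in 4 groups of 3: S2 cells with no treatment, S2 cells with double-stranded RNA (dsRNA) against Atx2, whole brains of 3rd instar larvae with no treatment named, and whole larval brains with Atx2 short hairpin RNA (shRNA) under elav gal4. Libraries were made with a TruSeq mRNA kit, per the labels' protocols. Each sample has 1 table of counts per gene, deposited by the authors. Adapters were trimmed with cutadapt 1.13, reads were aligned with STAR to BDGP6 and counted with HTSeq 0.6.1p1, per the submitters' processing notes, which also name DESeq2 without a role. The strand setting, the annotation release and any filters are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies (AttA and AttB, the Hsp70 genes, ribosomal protein copies) may be assigned in ways the counts do not show.

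All 12 tables hold the same 17737 gene identifiers and whole-number counts. Symbols, positions and exon lengths came from the BDGP6.54 annotation, which matched 17599 identifiers. The 138 identifiers without a match hold 0.995 to 1.39% of the counts of a library and stayed in the tests under their identifiers. Total counts were 14944637 to 29020252 per S2 library and 26442727 to 31579528 per brain library. Replicates were checked for duplicated libraries with a chi-square statistic of their counts, which was 24.1 to 165 per degree of freedom, so no pair differed by as little as sampling noise. Groups follow the labels, and no sample was left out.

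Counts were analysed in R 4.3.3 with edgeR 4.0.16. In each system, genes were kept by filterByExpr (minimum count 10), scaled by trimmed mean of M-values (TMM) and tested with the quasi-likelihood F test of edgeR (estimateDisp, glmQLFit, glmQLFTest, default settings). P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. Adjusted p-values of single genes come from this test unless another tool is named. A call at least 2-fold has a log2 fold change of at least 1 in size. The difference between the effects in brain and S2 cells was tested as an interaction in 1 fit of all 12 libraries. Calls shared between systems were compared with independent lists by 1-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Both sides were tested, and each side was adjusted separately over the combinations of directions. The side given is that of the observed difference, so these p-values are lower than those of a test of both sides at once. CPM are counts divided by TMM-scaled library sizes, and SE of a log2 fold change is the fitted coefficient divided by the root of F. Where a group held 0 counts, a fold is given as a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio has a 95% counting interval.

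Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, also with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a system. Lists with fewer than 3 measured members were not tested. The 36 lists were tubulins and tubulin cofactors, microtubule-associated and severing proteins, kinesins and adaptors, dynein and dynactin, actin cytoskeleton, neuronal and synaptic genes, axon guidance and neurite adhesion, neuropeptides, neuroblast and progenitor markers, cell cycle and replication, glial markers, fat body markers, muscle markers, hemocyte markers, salivary gland and glue markers, ring gland markers, imaginal disc and eye disc markers, cuticle and trachea genes, gut digestive enzymes, circadian clock genes, Ataxin-2 partners and RNA granule proteins, small RNA pathway genes, heat shock and protein folding, endoplasmic reticulum stress, apoptosis, JNK and damage response, innate immunity, ecdysone response and timing, insulin and TOR signalling, glycolysis, autophagy and lysosome, eye and body colour marker genes of transgenes, sex-linked transcripts, cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins, oxidative phosphorylation and proteasome subunits. Of their members 965 were matched and 16 were not. "Adjusted over the list alone" means Benjamini-Hochberg adjustment over the members of 1 list.

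The tests, the lists, the first set of alternatives and the rule for named genes were chosen before the data were examined. The rule takes Atx2, then in each system the 10 higher and 10 lower genes with the largest log2 fold change among called genes with a mean of at least 5 CPM in the higher group and non-overlapping groups. It adds up to 4 called members of each list with the largest change, 5 genes of each sign for the interaction, 5 higher and 5 lower genes called in both systems and 3 of each kind with opposite calls. Members of lists without a call may be named with their values.

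Alternatives were RLE and upper quartile scaling, no filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, a robust fit, limma-voom, the replicate number as a block, 1 fit of all 12 samples and leaving out each library in turn. Added after seeing the data were library totals alone as the scaling, S2 libraries thinned to equal totals, brain control 3 and brain knockdown 1 both left out, and a trend with exon length removed per library by loess (span 0.5).

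The fits were tested on simulated data drawn from the means and library sizes of the real samples, with 200 genes changed. In S2 cells, with 8906 genes, 64.3% of genes changed 2-fold and 92.9% of genes changed 4-fold were recovered, with 11 false calls among 165. In brain, with 10312 genes, these shares were 23.0% and 80.8%, with 8 false calls among 111. For the interaction, with 11016 genes, they were 19.0% and 55.1%, with 5 false calls among 78. Far more genes were called in the real data than were changed here, so these shares and false calls need not hold there. A shifted list was called in both systems, and 0 of 33 and 0 of 35 other lists were. The simulated genes were drawn independently of each other. The simulation therefore does not test the preset correlation on lists whose genes are correlated.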

Results

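Poly(A) RNA was measured in 12 samples of Drosophila melanogaster in 4 groups of 3. S2 cells, a cultured line of embryonic origin with properties of macrophage-like blood cells (hemocytes), received double-stranded RNA (dsRNA) against Atx2 or, by their labels, no treatment. Whole brains of 3rd instar larvae expressed, in the knockdown group, an Atx2 short hairpin RNA (shRNA) under the elav driver, which is active in neurons. The labels of the control brains name no treatment. Atx2 encodes Ataxin-2, a cytoplasmic RNA-binding protein. Total counts per library were 25994555 to 29020252 in S2 control cells and 14944637 to 20400465 in S2 cells with dsRNA. They were 29754856 to 31579528 in control brains and 26442727 to 28086056 in shRNA brains. Nothing in the labels says that replicates were separate cultures or separate animals, so p-values measure the spread between these samples, which may be technical. The series title names the cytoskeleton and neurodevelopment, and the comparisons ask which transcripts differ between knockdown and control libraries in each system.

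Atx2 (FBgn0041188, chromosome 3R, 15408423 to 15417277, plus strand) was lower in every knockdown library than in every control library of its system. In brain it fell from 193 ± 5.08 to 98.1 ± 5.86 CPM (counts scaled by library size; SD, n = 3), a log2 fold change of -0.98 ± 0.08 (SE; adjusted p = 0.00271). The control brains held 187, 195 and 197 CPM and the shRNA brains 92.4, 97.8 and 104.1 CPM. In S2 cells the control libraries held 242, 218 and 226 CPM, with a mean of 229 ± 12.5 (SD, n = 3). The dsRNA libraries held 149, 55.3 and 166 CPM, with a mean of 123.5 ± 59.7. The S2 log2 fold change was -0.89 ± 0.35, which did not pass the threshold (adjusted p = 0.0613). Reads of the dsRNA itself cannot be told from reads of the transcript in counts per gene. It passed without dsRNA library 1 (-1.06, adjusted p = 0.0461), dsRNA library 2 (-0.55, adjusted p = 0.0139) or dsRNA library 3 (-1.18, adjusted p = 0.0291). It did not pass without S2 control library 1 (-0.87, adjusted p = 0.114), library 2 (-0.96, adjusted p = 0.0962) or library 3 (-0.93, adjusted p = 0.107). It also passed with DESeq2 (adjusted p = 0.0140), while library totals alone as the scaling gave -0.41 (adjusted p = 0.311). It passed in 8 of 18 alternatives, over which the adjusted p for S2 cells ranged from 0.0139 to 0.311.

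**Figure D1:**
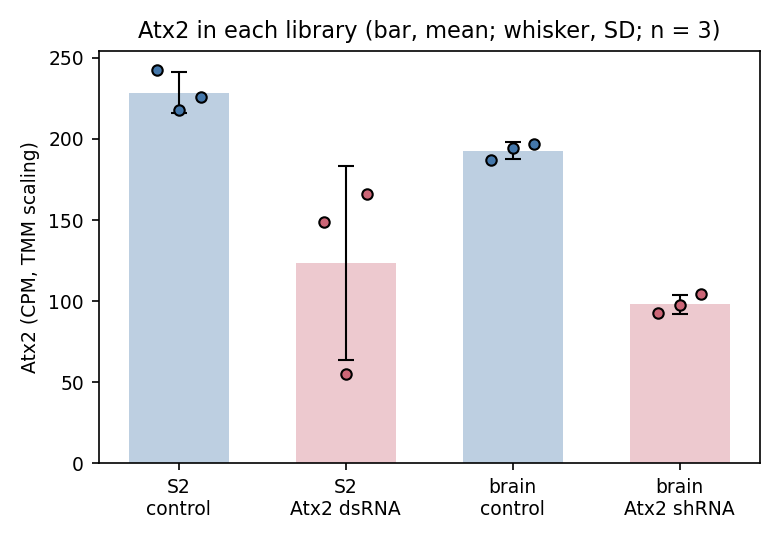
Atx2 in each of the 12 libraries, in CPM after TMM scaling (vertical axis), for control and knockdown groups of S2 cells and larval brain; points are libraries, bars are means and whiskers are SD (n = 3). The dsRNA libraries spread from 55.3 to 166 CPM, and the shRNA brains from 92.4 to 104.1 CPM.

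In S2 cells with Atx2 dsRNA, more genes of the innate immunity list were higher than lower, and genes for ribosomal proteins, cell division, glycolysis and hemocyte products were on balance lower. DptA (FBgn0004240, 2R, 18865765 to 18866260), an antimicrobial peptide gene, rose from 0.574 ± 0.287 to 58.0 ± 8.32 CPM (SD, n = 3), a log2 fold change of 6.64 ± 0.28 (adjusted p = 7.96e-06). Glt (FBgn0001114, 2L, 8672698 to 8676804), which encodes a secreted basement membrane glycoprotein, fell from 380.5 ± 45.9 to 8.90 ± 1.06 CPM (log2 -5.41 ± 0.16, adjusted p = 4.40e-06). RpS29 (FBgn0261599, 3R, 9778042 to 9779528), a protein of the small ribosomal subunit, fell from 3492 ± 159.5 to 232 ± 58.1 CPM (log2 -3.91 ± 0.19). CycA (FBgn0000404, 3L, 11826719 to 11833578), the cyclin of S phase and entry into mitosis, fell from 240.5 ± 42.8 to 53.2 ± 1.00 CPM (log2 -2.18 ± 0.15).

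Of 9058 genes tested in S2 cells, 4986 (55.0%) passed the threshold, 2580 higher and 2406 lower with dsRNA, and 2626 of them changed at least 2-fold (1401 higher and 1225 lower). With a stricter filter on low counts 1494 genes changed at least 2-fold, 587 higher and 907 lower, of 6879 tested. The libraries of the 2 groups did not overlap for 5777 genes (63.8%), where chance gives 10%. Directions depend on the scaling: library totals alone moved the median of all genes by 0.486 on the log2 scale and gave 4906 higher and 1324 lower genes, and upper quartile scaling gave 3406 and 1870. Among the 10 largest increases were Cyp6d2, a cytochrome P450 gene (log2 7.44 ± 0.74), and CG16713 (6.72 ± 0.66). CCAP-R, the receptor of crustacean cardioactive peptide, rose to 7.06 ± 2.70 CPM from a total of 2 counts in the control libraries, a ratio with a counting interval of 66.4 to 2000. The largest decreases were those of CG34330 (log2 -6.09 ± 0.74), fok (-5.45 ± 0.59), Glt and CG10433 (-5.37 ± 0.35).

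The innate immunity list had 31 measured members, of which 17 were higher, 6 lower and 8 not past the threshold (20 higher and 6 lower adjusted over the list alone). Besides DptA, the peptide genes AttD (log2 6.02 ± 0.60) and Def (5.31 ± 0.28) and the list member Srg2 (5.86 ± 0.88) rose. The list passed camera (median 1.33, adjusted p = 0.00199; adjusted p = 0.832 with an estimated correlation). The hemocyte list went the other way, with 9 of 12 members lower, 1 higher and 2 not past (9 and 1 adjusted over the list alone). The median was -1.45 (camera adjusted p = 5.75e-05; adjusted p = 0.285 with an estimated correlation). Hml (FBgn0029167, 3L, 13846054 to 13860001), the clotting protein hemolectin, fell from 1188 ± 385 to 129.9 ± 42.6 CPM (log2 -3.19 ± 0.31). The phagocytic receptor eater (-3.59 ± 0.32), the peroxidase Pxn (-3.21 ± 0.25) and the collagen IV gene vkg (-1.85 ± 0.14) fell as well.

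Cytoplasmic ribosomal protein genes fell as a group: 78 of 88 were lower, 5 higher and 5 not past (80 lower and 5 higher adjusted over the list alone). The median was -0.93 (camera adjusted p = 2.97e-14; adjusted p = 0.681 with an estimated correlation) and stayed below 0 with library totals alone, at -0.44. RpL37-2 (log2 3.09 ± 0.66) and RpS10a (2.16 ± 0.35) rose, to 1.64 ± 0.293 and 2.27 ± 0.756 CPM, low levels at which reads shared with their more abundant copies leave the value uncertain. In the cell cycle and replication list 21 of 31 genes were lower, 0 higher and 10 not past (22 lower adjusted over the list alone), and the median was -0.78 (camera adjusted p = 3.05e-05; adjusted p = 0.832 with an estimated correlation). Beside CycA, the mitotic kinase polo (log2 -2.07 ± 0.16) and the mitotic cyclin CycB (-1.74 ± 0.17) fell. In the glycolysis list 13 of 17 genes were lower, 0 higher and 4 not past (15 lower adjusted over the list alone). The median was -1.22 (camera adjusted p = 0.00136; adjusted p = 0.832 with an estimated correlation). Among the lower members were Ald1, fructose bisphosphate aldolase (489 ± 137 to 122 ± 79.9 CPM), sima, the oxygen-regulated subunit of hypoxia inducible factor (-2.04 ± 0.30), and Hph, the hydroxylase that marks it for breakdown (-2.72 ± 0.25).

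In the fat body list 4 of 8 genes were lower, 0 higher and 4 not past (5 lower adjusted over the list alone). The median was -0.67 (camera adjusted p = 0.00512; adjusted p = 0.495 with an estimated correlation). The members that fell act in lipid metabolism. FASN1 (FBgn0283427, 2L, 3056598 to 3068177), fatty acid synthase, went from 3392 ± 43.1 to 735 ± 72.5 CPM (log2 -2.21 ± 0.10), with the lipid transfer protein Apoltp (-2.74 ± 0.14) and the lipase bmm (-1.93 ± 0.15). In the insulin and TOR list 10 of 18 genes were lower, 1 higher and 7 not past (11 lower and 1 higher adjusted over the list alone). Sesn (log2 -3.39 ± 0.29), Thor (-2.08 ± 0.49), REPTOR (-1.67 ± 0.25) and ImpL2 (-1.61 ± 0.28), which restrain this pathway or act when it is off, were among the lower. The list's call (median -0.68, camera adjusted p = 0.0400, or 0.832 with an estimated correlation) was lost without S2 control library 1 (adjusted p = 0.0541). In 3 settings chosen after seeing the data it was also lost. These were library totals alone (adjusted p = 0.0686), the exon length trend removed (adjusted p = 0.0633) and S2 libraries thinned to equal totals (adjusted p = 0.0581). The adjusted p ranged from 0.00184 to 0.0686 over its alternatives.

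Of the cytoskeletal lists, the actin list had 20 of 44 genes lower, 4 higher and 20 not past (20 and 4 adjusted over the list alone). Gel, gelsolin (log2 -2.61 ± 0.15), the formin capu (-1.35 ± 0.17) and the Arp2/3 subunit Arpc3B (-1.98 ± 0.29) fell, and sn, the fascin that bundles filaments, rose (2.52 ± 0.49). Its call (median -0.42, camera adjusted p = 0.0400, or 0.832 with an estimated correlation) was lost without dsRNA library 1 (adjusted p = 0.101) and without S2 control library 2 (adjusted p = 0.0522). In settings chosen after seeing the data it was also lost. With library totals alone the median was 0.06 (adjusted p = 0.114). The adjusted p was 0.0878 with the exon length trend removed and 0.0652 with S2 libraries thinned to equal totals. The list passed in 6 of 11 alternatives, in a range of 0.0187 to 0.114. The list of microtubule-associated and severing proteins had 11 of 25 genes lower, 2 higher and 12 not past (12 lower and 2 higher adjusted over the list alone), and it did not pass camera (median -0.30, adjusted p = 0.168). Among its members stai, the tubulin-binding stathmin, fell from 163 ± 17.3 to 20.5 ± 4.73 CPM (log2 -2.99 ± 0.18), the spindle genes asp (-1.66 ± 0.21) and mars (-1.53 ± 0.15) fell, and the tubulin deacetylase HDAC6 rose (1.42 ± 0.15). Of 26 kinesins and adaptors 8 were higher, 9 lower and 9 not past, with the mitotic kinesins cmet (-1.84 ± 0.17) and ncd (-1.74 ± 0.18) among the lower (camera adjusted p = 0.707). Tubulins (4 of 12 higher, 3 lower) and dynein and dynactin (4 of 17 higher, 3 lower) did not pass camera (adjusted p = 0.842 for each).

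The dsRNA libraries held counts for 11896 to 12615 genes and the deeper control libraries for 11138 to 11627. The labels name no dsRNA for the control cells, so the effect of lowering Atx2 and that of receiving dsRNA cannot be separated here. None of the 8 list calls in S2 cells held with an estimated correlation between genes, where 0 of 33 lists passed after adjustment and 2, hemocyte and fat body markers, had an unadjusted p under the threshold. The test fry, which asks whether the genes of a list move one way on balance, called 13 lists, 8 of them shared with camera. The others were microtubule-associated and severing proteins as lower (fry adjusted p = 0.00492), and the imaginal disc, cuticle and trachea, ecdysone and colour marker lists as higher.

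In brains expressing Atx2 shRNA, neuroblast and neural progenitor genes were on balance lower than in control brains. Neuropeptide genes, neuronal and synaptic genes and genes of mitochondrial energy metabolism were on balance higher. erm (FBgn0031375, 2L, 1950239 to 1970362), a transcription factor of intermediate neural progenitors, fell from 66.5 ± 11.1 to 14.4 ± 2.59 CPM (SD, n = 3), a log2 fold change of -2.21 ± 0.18 (adjusted p = 0.00305). pros (FBgn0004595, 3R, 11328480 to 11407627), a transcription factor that ends neural progenitor division, fell from 1286 ± 173 to 431 ± 123 CPM (log2 -1.58 ± 0.22, adjusted p = 0.00759). The neuropeptide genes AstC (FBgn0032336, 2L, 11076165 to 11081399), from 11.9 ± 3.29 to 50.3 ± 4.54 CPM (log2 2.08 ± 0.21), and Mip (FBgn0036713, 3L, 17344947 to 17349666), from 14.0 ± 1.22 to 56.5 ± 12.96 CPM (2.01 ± 0.19), rose.

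Of 10438 genes tested in brain, 2397 (23.0%) passed the threshold, 1199 higher and 1198 lower with shRNA, and 703 of them changed at least 2-fold (542 higher and 161 lower). The libraries of the 2 groups did not overlap for 4646 genes (44.5%), where chance gives 10%. With the replicate number as a block 40 genes passed, 14 higher and 26 lower, though the labels do not say what the numbers mark. The count depends on single libraries: it was 494 without control library 2, 833 without shRNA library 2, 995 without control library 1, 1396 without shRNA library 1 and 1548 without control library 3. The count of genes changed at least 2-fold was 247 without control library 2, 320 without control library 1, 343 without shRNA library 2 and 434 without shRNA library 1. Among the largest decreases were Eip93F (FBgn0264490, 3R, 21949114 to 22014539), a transcription factor of late larval and pupal steroid responses, from 79.5 ± 13.2 to 6.96 ± 1.17 CPM (log2 -3.51 ± 0.18, adjusted p = 0.00122), and the glial and neuronal fate genes gcm (-2.46 ± 0.22) and gcm2 (-2.96 ± 0.27). FBgn0028993, an identifier for which no name or position was found in the annotation used, fell from 184 ± 17.2 to 28.0 ± 6.19 CPM (-2.71 ± 0.18). Among the largest increases were CG8245 (0.197 ± 0.0617 to 24.99 ± 1.75 CPM, log2 6.95 ± 0.25) and CG31808 (7.45 ± 0.43). Each of these 6 genes kept its call in all 6 fits that left out 1 library.

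Some brain libraries stood apart in genes of other tissues. The gut protease genes Jon65Aiv and Jon65Aiii were at 1397 and 610 CPM in shRNA library 1 and at most at 1.19 CPM in the other 5 libraries. The glue protein genes Sgs3 and Sgs5 of the salivary gland were at 632 and 555 CPM in control library 3 and at most at 12.5 CPM elsewhere. Lsp1beta, a fat body storage protein gene, was at 2706 CPM in shRNA library 1 and between 8.22 and 759 CPM elsewhere. Mhc, muscle myosin, was at 306 CPM in shRNA library 2 and between 6.84 and 70.4 CPM elsewhere. With control library 3 and shRNA library 1 both left out, an alternative chosen after seeing the data, 1231 genes passed in brain, 1095 of them shared with the 2397, and 17 gene lists passed camera, 16 of them shared.

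**Figure D2:**
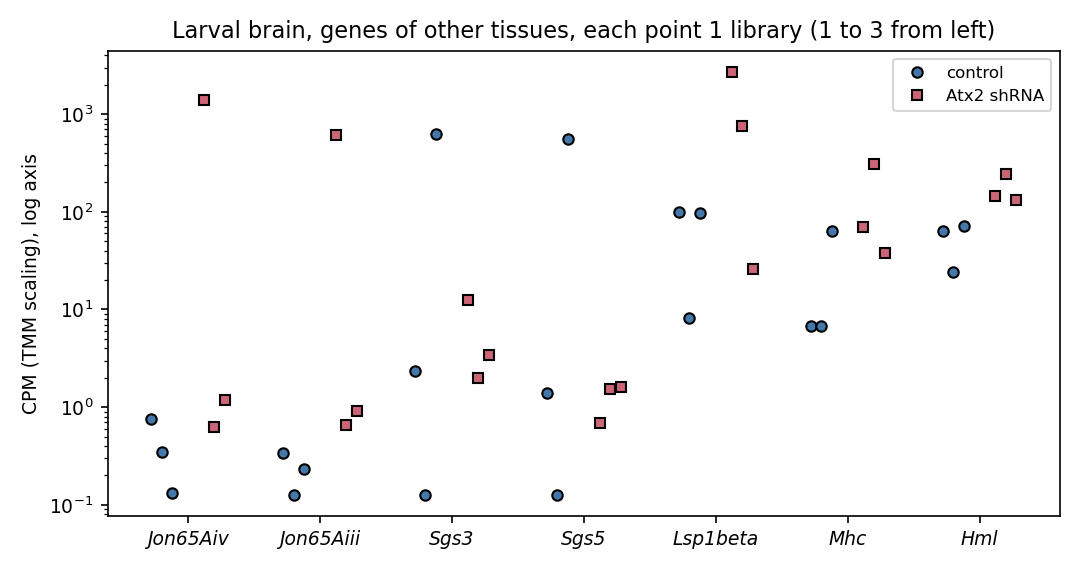
CPM after TMM scaling (vertical axis, log scale) of gut (Jon65Aiv, Jon65Aiii), salivary gland (Sgs3, Sgs5), fat body (Lsp1beta), muscle (Mhc) and hemocyte (Hml) genes in the larval brain libraries; each point is 1 library, control as circles and Atx2 shRNA as squares, replicates 1 to 3 from left. Jon65Aiv reached 1397 CPM in shRNA library 1 and Sgs3 reached 632 CPM in control library 3.

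In the list of neuroblast and progenitor markers 15 of 23 genes were lower, 1 higher and 7 not past the threshold (15 and 2 adjusted over the list alone). The median was -1.08 (camera adjusted p = 7.59e-10; adjusted p = 0.573 with an estimated correlation). Besides erm and pros, tll (log2 -1.97 ± 0.35) and ase (-1.35 ± 0.22), transcription factors of neural stem cells, fell. Neither kept its call when control library 2 was left out (-2.02, adjusted p = 0.0572, and -1.37, adjusted p = 0.0504). The cell cycle list had 8 of 31 genes lower, 0 higher and 23 not past (15 lower adjusted over the list alone). The median was -0.28 (camera adjusted p = 1.67e-05; adjusted p = 0.573 with an estimated correlation). CycE, the cyclin of entry into S phase, fell from 118 ± 6.01 to 62.5 ± 10.3 CPM (log2 -0.92 ± 0.13).

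Of 29 neuropeptide genes 21 were higher, 0 lower and 8 not past (22 higher adjusted over the list alone). The median was 1.10 (camera adjusted p = 9.75e-11; adjusted p = 0.573 with an estimated correlation). Dsk (FBgn0000500, 3R, 4189692 to 4190260), drosulfakinin, rose from 13.9 ± 0.317 to 50.6 ± 10.04 CPM (log2 1.86 ± 0.15). Of 37 neuronal and synaptic genes 13 were higher, 2 lower and 22 not past (18 and 2 adjusted over the list alone). The median was 0.41 (camera adjusted p = 5.63e-05; adjusted p = 0.573 with an estimated correlation). Rdl (FBgn0004244, 3L, 9145838 to 9182149), a GABA receptor subunit, rose from 86.0 ± 19.98 to 209 ± 25.6 CPM (log2 1.28 ± 0.19), and the potassium channel Shab rose (1.55 ± 0.26). Shab had no call without control library 2 (1.64, adjusted p = 0.0545). elav, the neuronal gene for which the driver is named, was chosen after its values were seen. It fell from 552 ± 62.3 to 336 ± 7.64 CPM (log2 -0.72 ± 0.10, adjusted p = 0.00732). In the axon guidance and neurite adhesion list 12 of 28 genes were lower, 0 higher and 16 not past (16 lower and 1 higher adjusted over the list alone). The median was -0.26 (camera adjusted p = 0.00013; adjusted p = 0.573 with an estimated correlation). The adhesion gene Dscam4 (log2 -0.95 ± 0.12) and the netrin receptor gene fra (-0.67 ± 0.09) fell, fra without a call in one fit of all 12 samples (-0.66, adjusted p = 0.215).

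**Figure D3:**
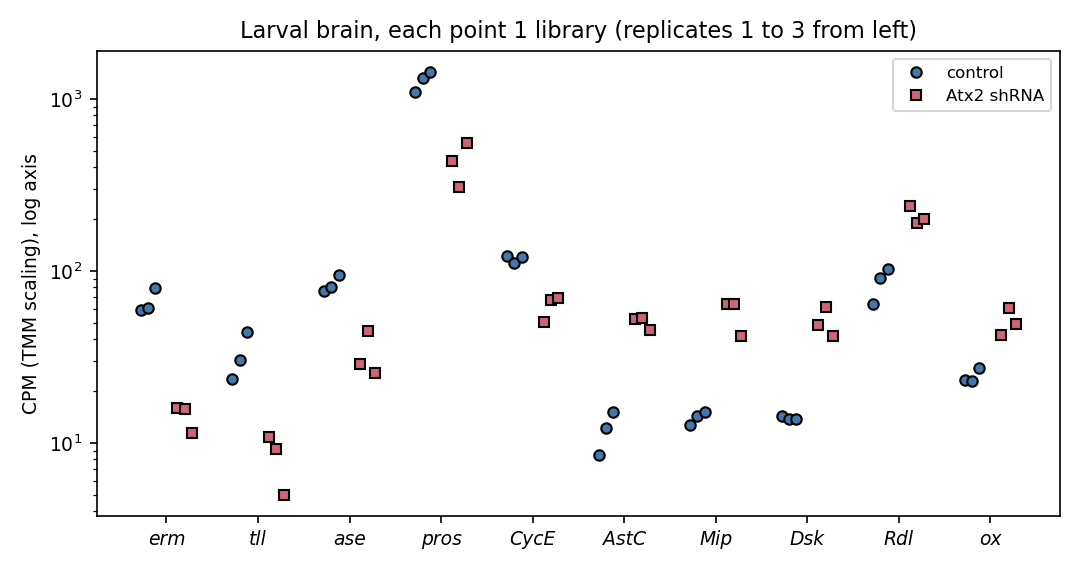
CPM after TMM scaling (vertical axis, log scale) of progenitor (erm, tll, ase, pros), cell cycle (CycE), neuropeptide (AstC, Mip, Dsk), GABA receptor (Rdl) and oxidative phosphorylation (ox) genes in the larval brain libraries; each point is 1 library, control as circles and Atx2 shRNA as squares. The fitted log2 fold changes run from -2.21 for erm to 2.08 for AstC, and for each gene shown the 2 groups do not overlap.

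Lists of energy metabolism were on balance higher in shRNA brains. Of 70 oxidative phosphorylation genes 31 were higher, 0 lower and 39 not past (46 higher adjusted over the list alone). The median was 0.40 (camera adjusted p = 7.59e-10; adjusted p = 0.573 with an estimated correlation). ox, a subunit of the cytochrome bc1 complex, rose from 24.4 ± 2.28 to 50.7 ± 9.41 CPM (log2 1.05 ± 0.15), and ND-B12, a complex I subunit, rose (0.70 ± 0.11). In the glycolysis list 13 of 18 genes were higher, 1 lower and 4 not past (14 and 2 adjusted over the list alone). The median was 0.93 (camera adjusted p = 7.97e-05; adjusted p = 0.573 with an estimated correlation). The muscle list passed in the same direction (median 1.71, adjusted p = 6.74e-05; adjusted p = 0.573 with an estimated correlation), with 0 of 16 members past the threshold singly in edgeR's test. Gapdh1 (log2 1.22 ± 0.24, adjusted p = 0.0163) had no call without control library 1 (1.14, adjusted p = 0.0634), control library 2 (1.10, adjusted p = 0.0703) or shRNA library 2 (1.11, adjusted p = 0.0609). Mitochondrial ribosomal protein genes were higher for 14 of 73, lower for 0 and not past for 59 (13 higher adjusted over the list alone). The median was 0.31 (camera adjusted p = 9.06e-08; adjusted p = 0.573 with an estimated correlation), among them mRpS6 (0.91 ± 0.12). Cytoplasmic ribosomal protein genes were higher for 18 of 85, lower for 2 and not past for 65 (29 and 2 adjusted over the list alone). The median was 0.25 (camera adjusted p = 1.41e-06; adjusted p = 0.604 with an estimated correlation).

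Partners of Ataxin-2 and RNA granule proteins were lower for 11 of 25 genes, higher for 0 and not past for 14 (16 lower and 1 higher adjusted over the list alone). The median was -0.29 (camera adjusted p = 6.99e-05; adjusted p = 0.573 with an estimated correlation). Fmr1, the fragile X RNA-binding protein, fell from 382 ± 12.2 to 248 ± 25.01 CPM (log2 -0.62 ± 0.09), and Pop2, a deadenylase subunit, fell (-0.56 ± 0.09). Neither had a call when control library 2 was left out (-0.61, adjusted p = 0.0558, and -0.51, adjusted p = 0.0574). The actin list had 13 of 45 genes lower, 2 higher and 30 not past (16 and 4 adjusted over the list alone; median -0.18, camera adjusted p = 0.00582; adjusted p = 0.573 with an estimated correlation). The gene pod1, which links actin and microtubules, fell from 714 ± 21.2 to 358 ± 50.9 CPM (log2 -0.99 ± 0.11). None of the microtubule lists passed camera. Microtubule-associated and severing proteins had 4 of 25 genes lower and 2 higher (adjusted p = 0.243), and Jupiter, a microtubule-binding protein, fell (log2 -1.08 ± 0.14). Kinesins had 2 of 27 lower and 1 higher (adjusted p = 0.360), tubulins 1 of 14 lower (adjusted p = 0.592), and dynein and dynactin 1 of 17 lower and 1 higher (adjusted p = 0.0933).

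The ecdysone list, genes of the steroid that times molts, had 7 of 19 genes lower, 2 higher and 10 not past (9 and 2 adjusted over the list alone; median -0.64, camera adjusted p = 0.00313; adjusted p = 0.573 with an estimated correlation), Eip93F among the lower. In the heat shock list 3 of 15 genes were lower, 1 higher and 11 not past (3 and 1 adjusted over the list alone), and its call (median -0.70, camera adjusted p = 0.0123; adjusted p = 0.573 with an estimated correlation) was lost without shRNA library 3 (-0.51, adjusted p = 0.0731; range 6.06e-05 to 0.0731). Hsp70Ba, one of several near-identical Hsp70 genes whose reads can be shared, rose to 3.25 ± 2.12 CPM from 3 counts in the control libraries, a ratio with a counting interval of 32.8 to 473. Proteasome subunits were lower for 5 of 33 genes, with 28 not past and 0 adjusted over the list alone, and the list's call (median -0.17, camera adjusted p = 0.0083; adjusted p = 0.654 with an estimated correlation) was lost without control library 1 (-0.13, adjusted p = 0.0677), without shRNA library 1 (-0.11, adjusted p = 0.128; range 0.000394 to 0.128) and with control library 3 and shRNA library 1 both left out (-0.12, adjusted p = 0.0731).

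The innate immunity, hemocyte and muscle lists passed camera as higher in shRNA brains, and the other lists of tissues outside the brain did not pass. Innate immunity genes were higher for 8 of 20, lower for 0 and not past for 12 (12 higher adjusted over the list alone). The median was 1.64 (camera adjusted p = 0.000177; adjusted p = 0.573 with an estimated correlation). The peptide gene IM33 was at 39.05, 21.8 and 0.28 CPM in shRNA libraries 1 to 3 and at most at 0.446 CPM in the controls (log2 6.20 ± 1.60, adjusted p = 0.0359). It kept its call in 1 of the 6 fits with 1 library left out, with an adjusted p of 0.118 without control library 1, 0.0767 without shRNA library 1, 0.117 without control library 2, 0.0878 without shRNA library 2 and 0.100 without control library 3. Hemocyte genes were higher for 5 of 17, lower for 0 and not past for 12 (6 higher adjusted over the list alone), among them the collagen IV genes vkg (log2 1.90 ± 0.30) and Col4a1 (1.81 ± 0.27). That list's call (median 0.82, camera adjusted p = 0.0317; adjusted p = 0.573 with an estimated correlation) was lost without shRNA library 3 (0.66, adjusted p = 0.126; range 5.28e-05 to 0.126). Muscle markers passed camera (median 1.71, adjusted p = 6.74e-05; adjusted p = 0.573 with an estimated correlation) with 0 of 16 members past the threshold singly, also adjusted over the list alone, in edgeR's test, where 13 had an unadjusted p under the threshold.

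**Figure D4:**
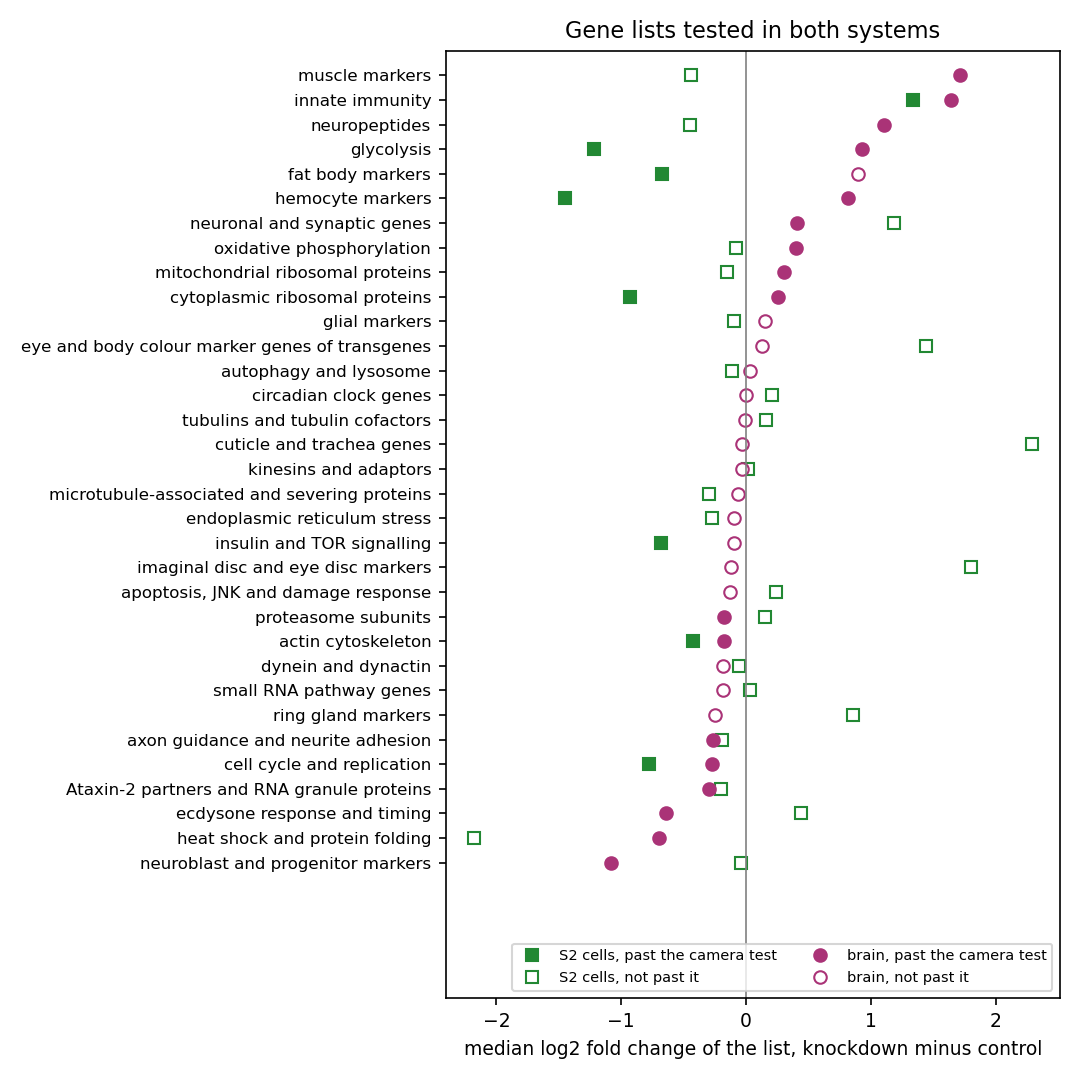
Median log2 fold change, knockdown minus control (horizontal axis), of each of the 33 gene lists tested in S2 cells and larval brain (vertical axis); squares are S2 cells, circles are brain, and filled symbols passed camera after adjustment over the lists of a system. Cytoplasmic ribosomal proteins lie at -0.93 in S2 cells and 0.25 in brain, and glycolysis at -1.22 and 0.93.

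The brain shRNA was expressed in part of the cells of the dissected tissue, so the fold changes are averages over cells with and without it. A change in the mix of cells cannot be told from a change within cells. The labels name no driver or shRNA for the control brains. The effect of lowering Atx2 and that of carrying the driver or an shRNA as such therefore cannot be separated here. None of the 17 list calls in brain held with an estimated correlation, with 0 of 35 lists past the threshold after adjustment and 2, neuropeptides and progenitor markers, before it. The test fry called 9 lists, 6 of them shared with camera. The others were dynein and dynactin as lower (fry adjusted p = 0.0288), and glial markers and circadian clock genes as higher. Among the lists called by camera, fry did not call actin (adjusted p = 0.0797), cell cycle (0.0797), neuronal and synaptic genes (0.0854) or glycolysis (0.0742), among others.

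The fold change between knockdown and control libraries differed between brain and S2 cells for 4595 of 11176 genes (41.1%) in a test of the difference itself, 2207 with the brain value above that in S2 cells and 2388 below. Library totals alone gave 1292 above and 4413 below, and upper quartile scaling gave 1859 and 3039. Cytoplasmic ribosomal protein genes (median difference 1.17, camera adjusted p = 3.07e-30), glycolysis genes (2.11, adjusted p = 4.25e-07) and hemocyte genes (1.35, adjusted p = 4.86e-05) lay higher in the brain fold changes than in those of S2 cells. Imaginal disc and eye disc markers lay lower (-1.97, adjusted p = 0.00061). Only 10 of these 17 genes passed the filter in S2 cells, with a median of 0.476 CPM in control cells. This difference therefore rests in part on low S2 values. With an estimated correlation the lowest adjusted p of any list was 0.435.

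Among the 8452 genes tested in both systems, 338 were lower in both (290 expected from independent lists, adjusted p = 0.00057 for more than that, 1-sided Fisher's exact test) and 195 were higher in both (248 expected, adjusted p = 5.12e-05 for fewer). A further 335 were lower in S2 cells and higher in brain (241 expected, adjusted p = 6.88e-13 for more), and 272 were higher in S2 cells and lower in brain (299 expected, adjusted p = 0.0558 for fewer). Genes lower in S2 cells thus lay above the expected number in both brain directions, and genes higher in S2 cells lay below it. Genes are not independent replicates, and across genes the fold changes of both systems had a Pearson correlation of 0.0107 and a Spearman correlation of -0.0309. Eip93F was among the genes lower in both, with log2 -2.21 ± 0.33 in S2 cells and -3.51 ± 0.18 in brain. CR43276 was higher in both (4.24 ± 0.51 and 2.98 ± 0.34). CG3397 was higher in both as well, at 9.17 CPM with dsRNA against 0.157 CPM in S2 cells, and at least 79.8-fold higher in shRNA brains, where the control libraries held 0 counts (floor of 3 counts over the group). Opposite calls were found for FBgn0028993 (log2 4.27 ± 0.67 in S2 cells and -2.71 ± 0.18 in brain), which held 3 counts in the S2 control libraries, a ratio with a counting interval of 7.21 to 110. It reached only 0.932 CPM with dsRNA, against 184 CPM in control brains. A share of brain reads in the dsRNA libraries, left open below, was not tested for this gene. The count of 533 genes changed in the same direction was 90 without brain control library 2 and 184 without brain shRNA library 2. It was 218 without brain control library 1 and 323 without brain shRNA library 1. With brain control library 3 and shRNA library 1 both left out it was 281. Directions in S2 cells depend on the scaling. Library totals alone gave 512 such genes, 346 of them among the 533, and upper quartile scaling gave 496, 414 of them among the 533. Opposite calls were not counted under other scalings.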

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

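The tests of a difference in depth, of scaling factors and of exposure to dsRNA, and the settings with library totals alone, thinned S2 libraries, brain control 3 and brain knockdown 1 both left out and the exon length trend removed, were chosen only after the result was seen.

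The fold change between knockdown and control libraries differed between brain and S2 cells for 4595 genes in the interaction test. In 100 drawn splits of treatment within each system, 1 gave as many, the real one, and the highest other gave 3595. The draws that kept the real S2 split reached 3595, those that kept only the brain split reached 16 and those that kept neither reached 8. The differences, brain minus S2 on the log2 scale, were largest upward for lcs (13.13 ± 3.39 SE, adjusted p = 0.00959), Dso1 (10.29 ± 2.16), CG34330 (9.32 ± 1.44), Hsp70Ba (9.14 ± 1.74) and CecC (8.96 ± 1.89). Fitted values of genes with few counts in a group are no measured folds: in brain the ratio was 2430 for lcs (2 control counts, interval 671 to 20000) and 173 for Dso1 (3 control counts, interval 58.9 to 843). In shRNA brains lcs was at 53.3 ± 92.2 CPM (SD, n = 3). Without brain shRNA library 1 the values fell to 3.94 for lcs, 6.34 for Dso1 and 5.65 for CecC, with the calls kept. lcs did not pass with limma-voom (7.19, adjusted p = 0.147). Downward they were largest for Uro (-8.27 ± 2.67, adjusted p = 0.0284), tw (-8.27 ± 0.72), sns (-7.84 ± 1.32), fj (-7.78 ± 1.30) and CG15369 (-7.77 ± 1.40). In S2 cells, tw had a ratio of 309 (1 control count, interval 55.0 to 12200), and sns and fj, at 0 in the controls, were at least 20.3-fold and 20.5-fold higher (floor of 3 counts over the group). With dsRNA sns and fj were at 0.925 and 0.923 CPM, against 92.8 and 84.2 CPM in control brains. A share of brain reads, left open below, was not tested for single genes.

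The value for Uro, brain minus S2 cells, turned to 0.92 (adjusted p = 0.678) without brain control library 1. It had no call without S2 control library 1 (-8.54, adjusted p = 0.0622), S2 control library 2 (-7.97, adjusted p = 0.0726), S2 control library 3 (-8.37, adjusted p = 0.0698), dsRNA library 3 (-7.67, adjusted p = 0.0593), shRNA library 1 (-7.81, adjusted p = 0.0508) or shRNA library 2 (-7.72, adjusted p = 0.0586), nor with limma-voom (-4.77, adjusted p = 0.192).

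In all, 9 gene lists differed between the systems by camera, with these median differences, brain minus S2: glycolysis 2.11, hemocyte markers 1.35, cytoplasmic ribosomal proteins 1.17, cell cycle and replication 0.53, mitochondrial ribosomal proteins 0.45, oxidative phosphorylation 0.44, insulin and TOR signalling 0.39, proteasome subunits -0.26, and imaginal disc and eye disc markers -1.97. With an estimated correlation the lowest adjusted p was 0.435. The imaginal disc difference rests in part on low S2 values, with a median of 0.476 CPM in control cells for the 10 members kept there. Insulin and TOR signalling passed in 11 of 17 other alternatives and proteasome subunits in 9 of 17. With library totals alone the medians of mitochondrial ribosomal proteins (-0.04) and oxidative phosphorylation (-0.04) changed sign with the call kept, because all genes shift by -0.474 between these scalings. Insulin and TOR signalling changed sign too and lost its call (-0.09, adjusted p = 0.103).

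In S2 cells the dsRNA libraries hold counts for more genes than the deeper control libraries. A difference in depth would favour the deeper control libraries, so depth alone does not give this direction. Thinning cuts mainly the control libraries and could be foreseen to widen the gap, so it adds no independent support. With all S2 libraries thinned to equal totals, the lowest dsRNA library held 918 more genes with a count than the highest control library. Reads from the brain libraries could contribute. Across 309 genes near 0 in S2 controls and well expressed in brain controls, S2 knockdown and brain control CPM had a Spearman rho of 0.17 (95% bootstrap interval 0.0545 to 0.285). The interval lay below 0.5, the bound written for brain reads as the cause, but not wholly under the bound written against them. Of the 309 genes, 10.7% reached 0.5 CPM with dsRNA, against 2.43% of 3576 genes near 0 in S2 controls and low in brain controls, which leaves this open. Of 230 genes with a count in every dsRNA library and in no S2 control library, 61 (26.5%) were higher there than in every brain library, which brain reads do not account for. Lower Atx2 itself stays open as an untested biological explanation.

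In S2 cells 4986 genes passed, 55.0% of those tested. Library totals alone gave 6230 genes, which met the bound written against scaling factors as the cause. That count cannot decide, because this scaling moved the median of all genes by 0.486 and gave 4906 higher and 1324 lower genes. Of the 4986 genes, 3904 passed in the same direction with both scalings. Cells of another S2 stock with other copy numbers may contribute: 11 of 86 windows of 100 neighbouring genes lay at least 0.3 from the median of all genes, against at most 1 in shuffled orders and 0 of 100 windows in brain. The SD of the window medians was 1.92 times that of shuffled orders, under the bound of 2 written against this explanation, while the count of windows met the bound written for it, which leaves it open. Exposure to double-stranded RNA as such cannot be told apart from lower Atx2, because 0 of the control libraries have labels that name another dsRNA. The splits of the 6 S2 libraries are too few for a share under 0.05 (1 of 10 splits gave as many): 4986 genes in the real split and 0 in the highest other, and 2626 and 0 at least 2-fold.

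In brain the progenitor list is lower and the neuropeptide, neuronal, glycolysis and oxidative phosphorylation lists are higher with shRNA by camera, and with an estimated correlation each loses its call (adjusted p = 0.573). A gene length trend between libraries is argued against, since with the exon length trend removed the progenitor median was -1.11 and the neuropeptide median 0.96. RNA of attached tissues in shRNA library 1 and control library 3 is argued against as well for the progenitor and neuropeptide lists alone, since without both the medians were -1.11 and 0.92. The muscle list passed camera in 11 of 11 alternatives, this one included. Attached muscle in other libraries was not tested for any of these lists, glycolysis and oxidative phosphorylation among them. A younger developmental stage of the shRNA brains may contribute and stays open beside lower Atx2, which is untested. For this test chinmo was at 0.50 (adjusted p = 0.0873), Imp rose (0.88, adjusted p = 0.0301) and Syp fell (-0.86, adjusted p = 0.0426). Outside the genes written for this test, Eip93F fell (-3.51 ± 0.18). The ecdysone list had 7 genes lower and 2 higher (median -0.64, camera adjusted p = 0.00313, or 0.573 with an estimated correlation). The splits of the 6 brain libraries are too few for a share under 0.05 (1 of 10 splits gave as many): 2397 genes in the real split and 8 in the highest other, and 703 and 8 at least 2-fold.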

How the results depend on the processing

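The tests with library totals alone, thinned S2 libraries, brain control 3 and brain knockdown 1 both left out and the exon length trend removed were chosen only after the result was seen. Of the results for named genes under settings other than a left-out library, 3278 kept direction and side of the threshold, 324 lost the call and 2 reversed, and with 1 library left out 1487 kept it, 423 lost it and 1 reversed. For gene lists these counts were 182 kept and 56 lost, and 241 kept and 17 lost. RLE scaling kept 353 of 353 results. DESeq2 gave no adjusted p for CG8997 in brain and for lcs, Dso1 and CecC in the interaction. In simulations with 200 genes changed, 64.3% of 2-fold changes were recovered in S2 cells, 23.0% in brain and 19.0% in the interaction. Far more genes were called in the data, so these shares need not hold there. The cause was not tested for the values below except where the setting itself gives it.

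Atx2 in S2 cells passed with DESeq2 (-0.91, adjusted p = 0.0140), limma-voom (-1.04, adjusted p = 0.0452), no filter (-0.94, adjusted p = 0.0211), the replicate block (-1.03, adjusted p = 0.0142) and one fit of all samples (-0.88, adjusted p = 0.0281), in a range of 0.0139 to 0.311 over its alternatives. The replicate block left 40 genes changed in brain (14 higher and 26 lower), 37 of them at least 2-fold, and 7 changed in both systems in the same direction. Residuals of libraries with the same number correlated at 0.381, 0.299 and -0.000965 in S2 cells and at 0.103, 0.249 and -0.468 in brain. Libraries with different numbers reached at most 0.238 in S2 cells and 0.425 in brain. With 3 libraries per group these values do not settle whether the numbers pair the libraries. The strict filter gave 1494 genes changed at least 2-fold in S2 cells, from fewer genes tested. With an estimated correlation, 0 lists passed in S2 cells and 0 in brain, and fry called 13 and 9. With brain control 3 and brain knockdown 1 both left out, 1231 genes changed in brain and 281 in both systems in the same direction. With library totals alone Xbp1 (0.035, adjusted p = 0.834) and ERp60 (0.21, adjusted p = 0.0938) reversed in S2 cells, and Uro reversed in the interaction without brain control library 1 (0.92, adjusted p = 0.678), its values ranging from -11.00 to 0.92 with 1 library left out.

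With 1 library left out, Atx2 ranged from -1.18 to -0.55 in S2 cells and from -1.01 to -0.93 in brain. Genes changed in S2 cells ranged from 3877 to 5466 and at least 2-fold from 2467 to 2832. Genes changed in brain ranged from 494 (without control library 2) to 2364 (without shRNA library 3) and at least 2-fold from 247 to 863. Genes changed in both systems in the same direction ranged from 90 to 604, interaction genes from 3909 to 4674, and lists called from 7 to 10 in S2 cells and from 17 to 18 in brain. Higher genes were 51.7% of the calls in S2 cells, 64.6% with upper quartile scaling and 78.7% with library totals alone, and for the interaction 48.0%, 38.0% and 22.6%.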

Other observations

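No test in this part was chosen after its result was seen. In S2 cells, lists of genes typical of other tissues had members that rose from low levels. The filter kept 10 of 17 matched imaginal disc, 26 of 37 neuronal and 6 of 15 cuticle and trachea genes. Members near 0 in control cells could pass it only through counts in the dsRNA libraries. The numbers of higher genes and the medians of these lists therefore follow in part from the filter. Of 10 imaginal disc and eye disc markers 8 were higher, 0 lower and 2 not past (median 1.80, camera adjusted p = 0.0662), with dpp, a secreted growth factor, at 0.171 CPM in control cells and 1.16 CPM with dsRNA (log2 2.70 ± 0.46). Of 26 neuronal and synaptic genes 13 were higher, 6 lower and 7 not past (median 1.18, adjusted p = 0.520), with nSyb, a synaptic vesicle protein, rising to 0.852 CPM (3.47 ± 0.47). Of 6 cuticle and trachea genes 4 were higher and 0 lower (median 2.29, adjusted p = 0.0811). The clock gene per rose (3.65 ± 0.27) and Pdp1 fell (-2.89 ± 0.17) in a circadian list with 2 of 11 higher and 2 lower (median 0.21, adjusted p = 0.842). aub, a piRNA pathway gene, rose (3.33 ± 0.22) and AGO2, of the siRNA pathway, fell (-1.15 ± 0.10), in a small RNA list with 3 of 12 higher and 2 lower (median 0.03, adjusted p = 0.842). egr, a tumor necrosis factor ligand, fell (-3.58 ± 0.16) in the apoptosis list, with 8 of 20 higher and 6 lower (median 0.24, adjusted p = 0.842, test direction down). In the Ataxin-2 partner list 3 of 25 were higher and 9 lower (median -0.20, adjusted p = 0.520).

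The other lists not called in S2 cells were axon guidance (8 of 21 higher, 10 lower, median -0.20, test direction up), neuropeptides (4 of 11 higher, 3 lower, median -0.45), progenitor markers (2 of 9 higher, 3 lower, median -0.04), glial markers (5 of 14 higher, 5 lower, median -0.10). Next came muscle markers (2 of 9 higher, 1 lower, median -0.44), ring gland (3 of 6 higher, 2 lower, median 0.86), heat shock (1 of 14 higher, 3 lower, median -2.18), endoplasmic reticulum stress (0 of 13 higher, 4 lower, median -0.27), ecdysone (6 of 13 higher, 2 lower, median 0.44). Adjusted over the list alone, 1 heat shock gene was higher and 9 were lower. The rest were autophagy (2 of 22 higher, 7 lower, median -0.11), colour markers (2 of 4 higher, 0 lower, median 1.44), mitochondrial ribosomal proteins (2 of 73 higher, 14 lower, median -0.15), oxidative phosphorylation (7 of 69 higher, 10 lower, median -0.08, mean 0.09, test direction down) and proteasome subunits (6 of 34 higher, 0 lower, median 0.15). Their adjusted p-values by camera ran from 0.359 to 0.847. The median and the test also differed in sign for kinesins (median 0.01, mean -0.10, test direction down) and dynein (median -0.06, test direction up). The mean lay on the other side of 0 for progenitor markers (0.14), glial markers (0.18) and muscle markers (0.35), each with test direction down. The salivary gland and gut lists had fewer than 3 measured members in S2 cells, and the sex-linked list had 2 in each system and was not tested. In these, lncRNA:roX1 rose (log2 2.12 ± 0.50) and lncRNA:roX2 fell (-1.24 ± 0.18) in S2 cells, and in brain they were at 0.39 (adjusted p = 0.248) and 0.04 (adjusted p = 0.891).

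In brain, glial markers were higher for 8 of 19 genes and lower for 2 (median 0.15, camera adjusted p = 0.125), with alrm, an astrocyte gene, rising from 137 to 333 CPM (log2 1.28 ± 0.15). In the imaginal disc list 0 of 17 were higher and 3 lower (median -0.12, adjusted p = 0.106), with the transcription factor genes ap (-1.75 ± 0.10) and ct (-0.72 ± 0.09) falling. In the small RNA list 2 of 12 were higher and 5 lower (median -0.19, adjusted p = 0.360), mean 0.10 and test direction down, AGO3 (1.70 ± 0.23) among the higher and loqs (-0.67 ± 0.09) among the lower. The clock gene tim rose (1.46 ± 0.22) in a circadian list with 3 of 13 higher and 2 lower (median -0.01, mean 0.35, test direction up), tim without a call in one fit of all 12 samples (1.48, adjusted p = 0.0627). The other lists not called were fat body (1 of 13 higher, median 0.89), salivary gland (0 of 10 past the threshold in edgeR's test, 3 with an unadjusted p under it, median -4.59), gut enzymes (1 of 8 higher, median 2.30). Adjusted over the list alone, 4 gut enzyme genes were higher and 0 lower. Further ones were ring gland (0 of 9 higher, 2 lower, median -0.25), cuticle and trachea (1 of 12 higher, median -0.04), endoplasmic reticulum stress (1 of 13 lower, median -0.10), apoptosis (2 of 23 higher, 6 lower, median -0.13, mean 0.04, test direction down), insulin and TOR (1 of 18 higher, 3 lower, median -0.10), autophagy (5 of 23 higher, 0 lower, median 0.03) and colour markers (1 of 7 higher, median 0.13). Their adjusted p-values by camera ran from 0.0772 to 0.656.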
